A study of Homo sapiens with 92 samples.

How the data were processed

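New RNA was measured by SLAM-seq. Cells take up 4-thiouridine (4sU), iodoacetamide alkylates it, and the labelled uridines are then read as T-to-C conversions. Per the labels, 4sU was given at 100 µM for 15 or 120 min, and libraries of total RNA were made after removal of ribosomal RNA. The 92 libraries fall into 32 groups of cells, drug, time and label. Per the submitters' processing notes, reads were aligned with HISAT, treated with Picard and counted with HTSeq on hg38, in an order and with options that the notes do not give.

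The deposited files give, per gene and library, counts of reads with a conversion and counts of all reads, both as whole numbers. They also hold, per the file headers, counts of T positions and a conversion rate, which is a fraction of converted T over all T covered. No deposited value was normalised across libraries. Each file lists only genes with at least 1 read, so a gene missing from a file was taken as 0 in that library. The files name 49186 genes, of which 279 on the Y chromosome or around the X inactivation centre were left out and 48907 were kept. Gene starts in the files sat 1 base below the reference start for 9208 of 28605 matched genes and were equal for 527, so 1 was added, and all positions are given in hg38. Of 52 clustered protocadherins 16 are listed in the files. Total counts per library ran from 10.7 to 114 M (M for 1e6 reads) for all reads and from 0.420 to 35.4 M for converted reads.

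Converted reads per gene were compared with edgeR's quasi-likelihood test on TMM-scaled counts, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes with low counts were removed with edgeR's own filter, at a minimum count of 10 and a total of 15. Libraries of a series shared 1 fit and 1 estimate of spread. The comparisons were dTAGV-1 against DMSO at each time, their average over 30 to 120 min and over 4 to 8 h, the drug effect from mitosis against that from release, and its dependence on time. DMSO libraries at 30, 60, 90 and 120 min were also compared with DMSO at 0 min, and these 4 comparisons share their 0 min libraries. The programs were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, data.table version 1.17.8, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

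The gene lists, the comparisons and the rule for naming genes were fixed before the data were examined. In each main comparison the rule took the 8 largest falls and the 8 largest rises among genes with an adjusted p under 0.05 and a mean log2 CPM of at least 3. Clone names were passed over, and a gene had to change in the same direction at each time averaged or have arms that did not overlap. The rule added up to 3 called members of each list, those with the largest change, and NIPBL. Of these, the text gives a selection. The 22 lists held immediate early genes, YAP and TEAD targets, TGF-beta response genes, inflammatory and NF-kB genes, extracellular matrix and adhesion genes, and mesenchymal and RPE-1 lineage transcription factors. They also held cohesin and its regulators, clustered protocadherins, mitotic genes, G1 and S phase genes, replication-dependent histones, p53 targets, stress and heat shock genes, cholesterol synthesis genes, ribosomal proteins, and housekeeping genes of transcription and RNA processing. The last 6 were markers of cardiomyocytes, neurons, neural progenitors and glia, pluripotent cells, fibroblasts and smooth muscle, and endothelium and endoderm. Lists were tested with limma's camera, two-sided, against all other tested genes at a preset correlation of 0.01, and again with an estimated correlation. Both p-values were adjusted over the lists of a comparison, and a list needed 3 tested members.

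Genes were called enriched in a cell type when their mean log2 CPM over both arms lay at least 2 above that in each other type. Their share among called genes was tested with Fisher's exact test, two-sided, and overlaps are given beside the number that chance would give. Neighbouring genes were counted within 500 kb of a gene's start, against 10000 draws of genes matched in level and length. Replicate numbers were taken to pair libraries where, with 3 or more pairs, each correlation of deviations from the group means was over 0.1. This held, from the data and not the labels, at 0 min of the mitosis series (0.194 to 0.564), after its 120 min of 4sU (0.152 to 0.581) and at 120 min of the release series (0.239 to 0.423). The share of converted reads was compared between arms with a two-sided exact permutation test.

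Alternatives were DESeq2's size factors, DESeq2's own test, no filter on low counts, the replicate number as a block, all reads in place of converted reads, totals of all reads as library sizes, each cell type or series alone, an absolute log2 change of at least 1, and leaving out each replicate. Chosen after seeing the data were each gene's converted reads relative to its all reads, replicates 1 and 2 or 3 and 4 alone, and fits without replicate 3 of DMSO at 120 min or of dTAGV-1 at 30 min. A block with crossed replicate numbers was also added then. The test was run on simulated data with 50 changed genes at each of 4 sizes of change. At a 2-fold change it recovered 94% in the average over 30 to 120 min with drug from mitosis, 94% at 4 to 8 h, 92% in the release average, 42% with 120 min of 4sU and drug from mitosis, and 74% in cardiomyocytes. Genes that had not been changed made up 2.82%, 7.44%, 2.45%, 11.3% and 10.9% of the calls, in the same order. At 4 to 8 h, with 120 min of 4sU and in cardiomyocytes, this share was above the threshold set for adjusted p. Calls in these comparisons may therefore hold more false genes than that threshold implies. The labels do not state whether replicates were independent experiments.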

Results

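The series asks what NIPBL does when transcription starts again after mitosis, and what it does in cells that no longer divide. NIPBL loads the cohesin ring on chromosomes and drives its extrusion of DNA loops. Most libraries came from clone NIPBL-D7 of hTERT RPE-1, an immortalised human retinal pigment epithelial line, in which NIPBL carries a green fluorescent protein and an FKBP12 degron. The compound dTAGV-1 brings this degron to the VHL ubiquitin ligase, and DMSO is its vehicle. Cells were held in S phase with thymidine, arrested in mitosis with nocodazole at 20 ng/ml for 120 min, shaken off and released.

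In the mitosis series the drug was present during the nocodazole block and after release. With 15 min of 4sU, this series had 3 DMSO and 4 dTAGV-1 libraries at 0 min, 3 and 3 at 30 min, 4 and 4 at 60 min, 4 and 4 at 90 min, 4 and 3 at 120 min, and 2 and 2 at each of 4, 6 and 8 h. In the release series the drug was given only for the time after release, with 3 and 3 libraries at each of 30, 60, 90 and 120 min. Each series also had 3 and 3 libraries at 120 min with 4sU for the full 120 min. Cardiomyocytes and neurons made from WTC11, a human induced pluripotent stem cell line, were treated for 4 h and labelled for 120 min, with 2 and 2 libraries per cell type. Titles and growth protocol name WTC11 for these libraries, while another label field names RPE-1, and the titles were followed. The titles name no NIPBL tag in these cells, so the degron in them is assumed from the use of dTAGV-1. Group means of converted reads ran from 1.39 M in DMSO at 0 min to 21.5 M in DMSO of the release series with 120 min of 4sU. Replicate 3 of DMSO at 120 min in the mitosis series stood apart, with 13.4% of its converted reads in 10 genes against 3.44% to 3.75% in the other 3.

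For the share of reads with a conversion, no difference between arms passed a two-sided exact permutation test, with adjusted p = 1 throughout. It was 2.66% ± 0.237 (SD, n = 4) with dTAGV-1 and 2.78% ± 0.474 (n = 3) with DMSO at 0 min of the mitosis series. At 120 min of that series it was 3.76% ± 0.428 (n = 3) and 3.76% ± 0.482 (n = 4), and in cardiomyocytes 28.0% ± 1.20 (n = 2) and 29.2% ± 0.415 (n = 2). In neurons it was 20.9% ± 0.0532 and 23.0% ± 1.66, and at 6 h 5.99% ± 0.560 and 7.05% ± 0.773 (n = 2 each). The smallest p that the exact permutation test could give was 0.0286 with 4 libraries in an arm, 0.1 with 3 and 3, and 0.333 with 2 and 2, so after adjustment over the groups no difference could have passed. No library without 4sU is among those used here, so the share that is background is not known. The degron acts on the protein, so NIPBL RNA does not show whether the drug worked. NIPBL transcripts (ENSG00000164190) rose by 0.36 ± 0.07 (SE) on the log2 scale at 4 to 8 h, with adjusted p = 0.00204. They passed the test in no other main comparison, with −0.02 ± 0.17 in the release series after 120 min of 4sU and 0.17 ± 0.11 over 30 to 120 min in the mitosis series.

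**Figure D1:**
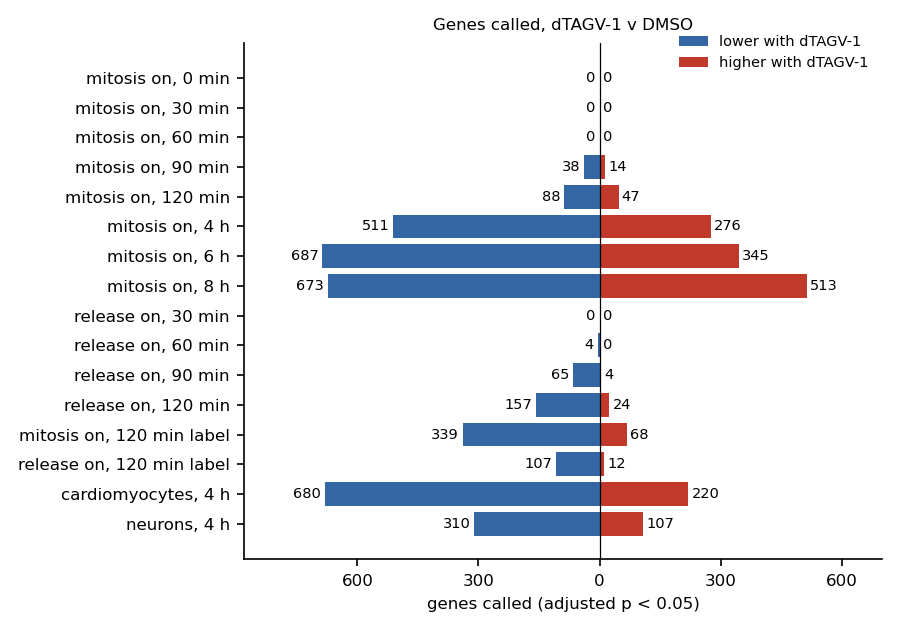
Genes called lower (left bars) and higher (right bars) with dTAGV-1 than with DMSO in each comparison, counted at an adjusted p under 0.05. With the filter on low counts no gene passed at 0, 30 or 60 min with drug from mitosis, against 88 lower and 47 higher genes at 120 min and 680 lower and 220 higher in cardiomyocytes.

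How RPE-1 cells took up transcription again was followed in DMSO, from 0 min to 120 min after release. Mitotic genes fell, with TOP2A, a topoisomerase of chromosome condensation, at −3.05 ± 0.27 and the mitotic kinase CDK1 at −4.59 ± 0.36 on the log2 scale (4 libraries against 3). CDK1 went from 307 ± 74.3 to 13.9 ± 5.23 CPM (normalised read count, mean ± SD). Interleukin gene IL1A rose by 5.23 ± 0.68, the stress gene DDIT4 by 4.51 ± 0.51, and SNAI2, a transcription factor of mesenchymal cells, by 4.13 ± 0.52. IER3, an early response gene, rose by 4.35 ± 0.60 and the transcription factor gene GATA6 by 2.54 ± 0.30.

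By list, 22 of 28 mitotic genes fell and none rose (25 adjusted over the list alone), among them UBE2C, which marks mitotic proteins for degradation, at −2.34 ± 0.33. Of 17 p53 targets 12 rose (12 adjusted over the list alone), with SESN2 at 3.20 ± 0.43 and the cell cycle inhibitor CDKN1A at 2.66 ± 0.43. Both lists also passed with an estimated correlation, with adjusted p = 0.0452 and 0.0139. Of 18 inflammatory genes 14 rose, with IL6 at 3.72 ± 0.61 and LIF at 3.62 ± 0.62. Replication-dependent histone genes rose in 18 of 22, HIST1H1E by 4.75 ± 0.84, and ribosomal protein genes in 53 of 79 against 1 that fell, RPL37A by 1.61 ± 0.19. Cohesin and its regulators fell in 6 of 17, PDS5B by 1.05 ± 0.19 on the log2 scale. These 4 lists passed with the preset correlation, and adjusted p = 0.132 for each with an estimated correlation. Immediate early genes rose in 15 of 28 and fell in 1, mesenchymal and lineage factors rose in 19 of 30, TGF-beta genes in 9 of 16, stress genes in 10 of 19 and matrix genes in 6 of 25. With an estimated correlation their adjusted p was 0.219, 0.12, 0.12, 0.12 and 0.182. The other 9 lists tested did not pass, and the median of G1 and S phase genes turned from −0.11 to 0.26 under scaling by all reads.

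Relative to all reads of each gene, 17 of the genes named by rule changed sign, among them IL6 at −0.16 and HIST1H1E at −0.24. In numbers, 1872 genes were lower and 2081 higher at 120 min than at 0 min, out of 14208 tested. At 60 min 1974 were lower and 3131 higher, and at 90 min 1420 and 2026. At 30 min no gene passed, with 497 at an unadjusted p under 0.05 in edgeR and none called by DESeq2, while edgeR without the filter on low counts called 72. Scaled by all reads, the median of all genes moved by 0.415 at 120 min, and 868 genes were lower and 3929 higher. Without replicate 4, 2489 genes were called in place of 3953, and 2515 without replicate 2. At 60 min these counts were 2976 and 3372, and at 90 min 2021 without replicate 4.

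With drug from mitosis, VEGFA and AKAP12 were among the genes that fell most over 30 to 120 min after release. VEGFA, a growth factor of blood vessels (hg38 chromosome 6, 43770184 to 43786487), fell by 1.36 ± 0.13 on the log2 scale, from 213 to 61.6 CPM (15 DMSO and 14 dTAGV-1 libraries, adjusted p = 1.1e-08). AKAP12, a scaffold of protein kinase A (hg38 chromosome 6, 151239999 to 151358557), fell by 1.26 ± 0.10, from 635 to 215 CPM. In each average over times, the CPM are means over the times and the log2 change is the mean of the changes at each time. The CPM and the log2 change therefore need not match. The transcription factor gene MYC was at −1.05 ± 0.15, IL6 at −1.43 ± 0.28, HAS2, which makes hyaluronan, at −1.18 ± 0.23 and SNAI2 at −1.84 ± 0.28. Genes that rose included NR4A3, a nuclear receptor gene, at 1.26 ± 0.30, MAP3K8, a kinase of inflammatory signalling, at 1.10 ± 0.21, and the transcription factor gene TFAP2A at 0.88 ± 0.14. STAG1, a subunit of cohesin, rose by 0.42 ± 0.11, with adjusted p = 0.0490.

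The falls came late in this window. VEGFA was at −0.25 ± 0.29 at 30 min and −0.48 ± 0.23 at 60 min, neither past the test, and fell by 2.17 ± 0.23 at 90 min and 2.54 ± 0.26 at 120 min. AKAP12 was at −0.15, −0.63, −2.12 and −2.13 at these times, and SNAI2 at 0.45, −0.82, −3.12 and −3.89. The change depended on time for 8 genes, among them AKAP12, VEGFA, the hypoxia factor HIF1A, PTX3 and SNAI2. This count was 5, 2 and 1 with replicates 1, 2 and 4 left out in turn, and 15 without replicate 3 of DMSO at 120 min. GATA6, a transcription factor of heart and endoderm, fell by 1.29 ± 0.24 at 90 min and by 1.36 ± 0.27 at 120 min.

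Among the lists, 3 of 18 inflammatory genes fell (5 lower and 2 higher adjusted over the list alone), as did 3 of 28 immediate early genes (3 adjusted over the list alone). Matrix and adhesion genes split into 3 lower and 1 higher of 25, with the collagen gene COL5A2 at −0.83 ± 0.10. These lists passed with the preset correlation, yet their medians were −0.02, −0.02 and −0.01 and turned to 0.04, 0.05 and 0.04 under scaling by all reads. With an estimated correlation the adjusted p was 0.654, 0.654 and 0.617. Of 30 mesenchymal and lineage factors 7 rose, TFAP2A among them, and 4 fell (adjusted p = 0.617 with an estimated correlation). Mitotic, G1 and S phase, ribosomal protein, cohesin and cardiomyocyte lists passed with the preset correlation with 0 or 1 called member each, and with an estimated correlation their adjusted p was 0.654, 0.617, 0.654, 0.617 and 0.502. The other 11 lists tested did not pass.

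Over 30 to 120 min 107 genes were lower and 73 higher with dTAGV-1. By time, 38 were lower and 14 higher at 90 min and 88 and 47 at 120 min. With replicates 1, 2 and 4 left out in turn the called genes were 33, 16 and 11 at 90 min and 64, 23 and 29 at 120 min. With the replicate number as a block, or without the filter on low counts, more genes were called at 90 min, at 120 min and in the average. No gene passed at 0, 30 or 60 min in edgeR, with 355, 195 and 155 at an unadjusted p under 0.05, nor in DESeq2, while without the filter on low counts edgeR called 27, 7 and 7. At 0 min the deviations of libraries with the same number went together, and with the number as a block 0 genes passed as well, with 420 at an unadjusted p under 0.05. Scaled by all reads, the average gave 53 lower and 58 higher genes. It gave 57 called genes without replicate 4, 63 without replicate 2 and 110 without replicate 1, while replicates 1 and 2 alone gave 86 lower and 11 higher genes and replicates 3 and 4 alone 37 and 33.

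**Figure D2:**
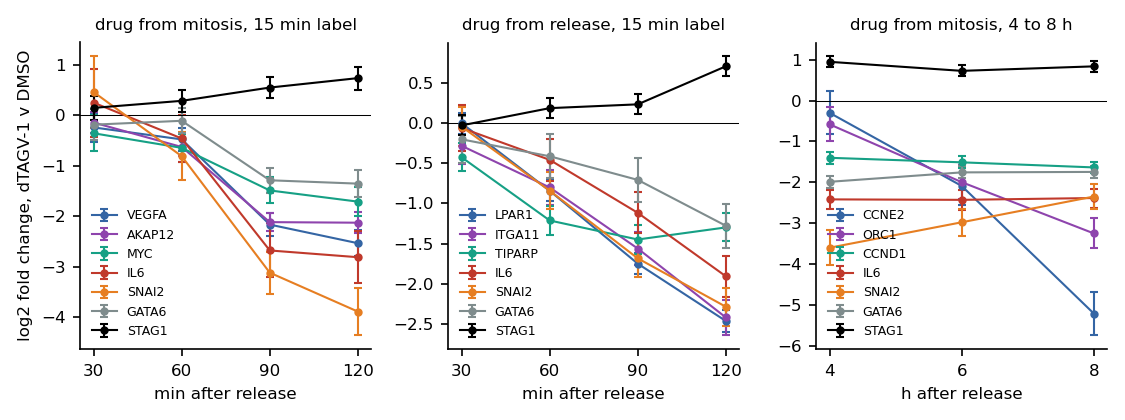
Log2 fold change of dTAGV-1 over DMSO (points, with SE as bars) against time after release for 7 genes in each series. SNAI2 went from 0.45 at 30 min to −3.89 at 120 min with drug from mitosis, and CCNE2 from −0.30 at 4 h to −5.21 at 8 h.

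From 4 to 8 h after release, the largest falls with drug from mitosis were those of MN1, EDN1 and PTX3. EDN1, the endothelin gene, fell by 4.64 ± 0.14 on the log2 scale, from 137 to 5.43 CPM (6 libraries against 6, adjusted p = 4.9e-13). LPAR1, a receptor for lysophosphatidic acid, fell by 3.02 ± 0.11, from 600 to 74.7 CPM, PTX3, a secreted pentraxin, by 4.07 ± 0.12, and BMP2, a bone morphogenetic protein, by 3.35 ± 0.20. MN1, a transcriptional coregulator, fell by 5.29 at 6 h and by 4.58 at 8 h, and at 4 h the 2 dTAGV-1 libraries held 0 converted reads of it. Genes that rose included the RNA LINC01510, at 2.56 ± 0.20, KCTD4 at 2.53 ± 0.20, the oxidation enzyme CYP1B1 at 2.03 ± 0.11 and the haem oxygenase gene HMOX1 at 1.75 ± 0.16.

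Genes of G1 and S phase fell in 15 of 26 and rose in 1 (19 and 1 adjusted over the list alone), with a median of −0.82. Cyclin gene CCNE2 was at −0.30 at 4 h, fell by 2.09 at 6 h and by 5.21 at 8 h, and ORC1, of the origin recognition complex, was at −0.58, −2.00 and −3.25. CCND1, the cyclin of early G1, fell by 1.52 ± 0.08. Of 19 YAP and TEAD targets 11 fell and none rose (11 and 1 adjusted over the list alone), with TGFB2 at −2.05 ± 0.12 and the clotting factor gene F3 at −1.29 ± 0.08. The list tests gave adjusted p = 2.07e-10 and 7.06e-05, but 0.0757 for each with an estimated correlation. Matrix genes fell in 11 of 25 and rose in 2 (11 and 3 adjusted over the list alone), with HAS2 at −2.64 ± 0.14 and VCAN at −1.51 ± 0.10 (adjusted p = 0.18 with an estimated correlation). In the TGF-beta list 5 of 16 fell, led by the matrix protein gene THBS1 at −2.65 ± 0.20 (adjusted p = 0.41 with an estimated correlation).

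Inflammatory genes went both ways, with 7 lower and 6 higher of 18 (7 and 10 adjusted over the list alone). IL6 fell by 2.41 ± 0.14 and IL1B by 2.31 ± 0.12, and the list's test and mean of −0.17 pointed down while its median was 0.29 (adjusted p = 0.345 with an estimated correlation). Mesenchymal and lineage factors also split, with 10 lower and 11 higher of 31, a median of 0.03 that turned to −0.01 under scaling by all reads, a mean of −0.20 and no call. Of 17 p53 targets 6 rose and 1 fell, TP53INP1 at 0.55 ± 0.09, and 4 of 19 stress genes rose, with adjusted p = 0.25 and 0.586 with an estimated correlation. Cardiomyocyte markers fell in 2 of 6, GATA6 by 1.83 ± 0.08 (adjusted p = 0.0757 with an estimated correlation). Mitotic genes passed upwards with 1 called member of 28 (adjusted p = 0.823 with an estimated correlation). Among cohesin genes STAG1 rose by 0.84 ± 0.08 and STAG2 by 0.34 ± 0.08, though this list and the other 10 tested did not pass.

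Together the 3 times gave 1562 lower and 1322 higher genes of 14572, with 511 and 276 at 4 h, 687 and 345 at 6 h and 673 and 513 at 8 h. Scaled by all reads the counts were 1314 lower and 730 higher. Relative to all reads of each gene, 174 genes were called, LINC01510 was at −0.0950 and IL1B at 0.0334.

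After 120 min of 4sU with drug from mitosis, AKAP12 fell by 3.20 ± 0.33 on the log2 scale, from 3385 ± 1146 to 368 ± 103 CPM (SD, 3 libraries each, adjusted p = 7.8e-05). SNAI2 fell by 3.04 ± 0.26, IL6 by 3.07 ± 0.31, and HS3ST1, a heparan sulfate sulfotransferase gene, by 3.28 ± 0.34. Genes that rose included MYLIP, a ubiquitin ligase of the LDL receptor, at 1.34 ± 0.24, the peptide hormone gene ADM at 1.28 ± 0.30 and the eye field factors OTX2 at 1.15 ± 0.23 and PAX6 at 0.98 ± 0.17. Inflammatory genes fell in 7 of 20 (9 adjusted over the list alone), with IL1A at −2.48 ± 0.17 and the chemokine gene CXCL1 at −2.52 ± 0.40. Matrix genes fell in 8 of 25 (11 lower and 1 higher adjusted over the list alone), with COL5A2 at −2.04 ± 0.20 and VCAN at −1.75 ± 0.24. Both lists passed with an estimated correlation, each with adjusted p = 0.04. Histone genes and p53 targets passed upwards with 0 called members (adjusted p = 0.836 and 0.641 with an estimated correlation), and the other 16 lists tested did not pass. With the pair as a block YAP targets passed downwards as well, at adjusted p = 0.0228. CCND1 fell by 1.45 ± 0.26 and CDK6, its kinase partner, by 1.06 ± 0.21.

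In this comparison 339 genes were lower and 68 higher of 16573. Replicate numbers paired these libraries, and with the pair as a block 833 genes were called. The count was 76 without replicate 2, 142 without replicate 1 and 263 without replicate 3, and with all reads in place of converted reads it was 66. DESeq2 called 656, and edgeR 212 scaled by all reads and 165 with this series fitted alone.

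With drug only from release, the average over 30 to 120 min showed falls in LPAR1 of 1.26 ± 0.07, from 525 to 257 CPM (12 libraries against 12, adjusted p = 2.9e-11). ITGA11, a collagen receptor, fell by 1.27 ± 0.11, SNAI2 by 1.21 ± 0.12, UGCG, which makes glucosylceramide, by 1.15 ± 0.09, and TIPARP, an ADP-ribosyl transferase gene, by 1.10 ± 0.09. Rises were smaller, with OTX2 at 0.87 ± 0.15, MAB21L2 at 0.79 ± 0.17, the GTPase gene GEM at 0.75 ± 0.14 and STAG1 at 0.27 ± 0.06. LPAR1 was at −0.00 at 30 min and fell by 0.84 at 60 min, 1.75 at 90 min and 2.46 at 120 min. TIPARP fell by 1.21 at 60 min, and SNAI2 first passed the test at 90 min, at −1.68.

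Inflammatory genes fell in 6 of 16 (6 adjusted over the list alone), with IL1A at −0.94 ± 0.08 and the prostaglandin enzyme PTGS2 at −0.68 ± 0.13. Matrix genes fell in 5 of 25 (8 adjusted over the list alone), with HAS2 at −0.75 ± 0.10 and LAMC1 at −0.46 ± 0.06. Both passed with an estimated correlation, each with adjusted p = 0.0065. YAP targets fell in 2 of 19 (5 adjusted over the list alone), immediate early genes in 1 of 24 and cardiomyocyte markers in 1 of 6, with adjusted p = 0.266, 0.521 and 0.0627 with an estimated correlation. Cholesterol synthesis and p53 lists passed upwards and G1 and S phase and ribosomal protein lists downwards, with 0 called members each. With an estimated correlation their adjusted p was 0.185, 0.521, 0.521 and 0.641, and the medians of the last pair turned from −0.11 and −0.08 to 0.01 and 0.02 under scaling by all reads. The other 11 lists tested did not pass.

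The release series gave 226 lower and 67 higher genes of 13929. No gene passed at 30 min in edgeR (295 at an unadjusted p under 0.05), 4 were lower at 60 min, 65 lower and 4 higher at 90 min, and 157 and 24 at 120 min. Scaled by all reads, the median of all genes moved by 0.115 and 62 genes were called. Without replicate 2 there were 106 called genes and without replicate 1 there were 118, and with the replicate number as a block 495.

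After 120 min of 4sU in the release series, LPAR1 fell by 2.11 ± 0.22, from 534 ± 129 to 124 ± 8.54 CPM (SD, 3 libraries each, adjusted p = 0.00055). ITGA11 fell by 2.21 ± 0.27, SNAI2 by 1.83 ± 0.24 and the neurotrophin gene BDNF by 1.75 ± 0.29. KCTD4 rose by 1.51 ± 0.24, MAB21L2 by 1.25 ± 0.17, OTX2 by 1.16 ± 0.23 and PAX6 by 0.80 ± 0.17. Inflammatory genes fell in 5 of 20 (6 adjusted over the list alone), with NFKBIZ at −1.25 ± 0.12, and matrix genes in 3 of 25 (7 lower and 1 higher adjusted over the list alone). With an estimated correlation their adjusted p was 0.0936 and 0.0976. Cholesterol synthesis genes passed upwards with a median of 0.34 and 0 called members of 17 (4 adjusted over the list alone, adjusted p = 0.0936 with an estimated correlation). Histone, stress and ribosomal protein lists passed upwards with 0 called members and cardiomyocyte markers downwards with 1 of 10 (adjusted p = 0.597, 0.597, 0.932 and 0.344 with an estimated correlation). The other 13 lists tested did not pass. Of 16573 genes 107 were lower and 12 higher, and 2 were called without replicate 2 and 27 without replicate 1. DESeq2 called 256, edgeR scaled by all reads 50, with all reads in place of converted reads 23 and with the replicate number as a block 282.

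Whether drug from mitosis acts differently from drug at release was tested as the difference between their effects over 30 to 120 min. The effect was lower with drug from mitosis for AKAP12, with a difference of −0.97 ± 0.16 on the log2 scale, and VEGFA at −0.85 ± 0.17. It was lower with drug from release for LPAR1, with a difference of 0.73 ± 0.14, the ephrin gene EFNB2 at 0.88 ± 0.13 and the ephrin receptor gene EPHA4 at 0.71 ± 0.13. The difference passed for 14 genes of 14726, with 5 below 0 and 9 above, and for 2, 2, 7 and 8 with replicates 1, 2, 3 and 4 left out in turn. The series are separate sets of libraries, so the drug's timing cannot be separated from other differences between the sets. In DMSO the share of converted reads was higher in the release series, at 4.77% against 2.77% at 30 min and 7.11% against 3.76% at 120 min. Background among converted reads could thus shrink log2 changes more in the mitosis series, which was not tested. After 120 min of 4sU no gene passed this test in edgeR, with 495 at an unadjusted p under 0.05. DESeq2 called 21, edgeR without the filter on low counts 36, and edgeR with the replicate number as a block 14.

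In cardiomyocytes, cholesterol synthesis genes rose together after 4 h of drug. INSIG1, a sterol sensor, rose by 2.08 ± 0.12 on the log2 scale, from 29.4 ± 1.22 to 124 ± 9.79 CPM (SD, 2 libraries each, adjusted p = 4.7e-06). HMGCS1, an early enzyme of the pathway, rose by 1.58 ± 0.08, from 167 to 499.6 CPM, and STARD4, a sterol carrier, by 1.38 ± 0.10. Relative to all reads of each gene, INSIG1 was at −0.00286, HMGCS1 at 0.31 and STARD4 at 0.55. RGS4, a regulator of G protein signalling, fell by 3.30 ± 0.14, from 64.6 to 6.55 CPM, and INHBA, a subunit of activin, by 3.00 ± 0.16. Among heart genes, the myosin gene MYH7 stood at −1.57 ± 0.25, the natriuretic peptide gene NPPB at −1.50 ± 0.35 and MYOCD, a coactivator of muscle genes, at −1.28 ± 0.18.

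Of 18 cholesterol synthesis genes 16 rose and none fell (17 adjusted over the list alone), with a median of 1.18 and adjusted p = 0.0103 with an estimated correlation. YAP targets fell in 7 of 19 (10 adjusted over the list alone), with IGFBP3 at −1.70 ± 0.14 and TGFB2 at −1.47 ± 0.09. Matrix genes fell in 6 of 31 (10 adjusted over the list alone), with CDH11 at −1.92 ± 0.12, immediate early genes in 4 of 28 (10 adjusted over the list alone), with JUN at −0.87 ± 0.15, and fibroblast and smooth muscle markers in 3 of 12 (6 adjusted over the list alone), with TAGLN at −1.17 ± 0.24. With an estimated correlation their adjusted p was 0.127, 0.196, 0.427 and 0.0666. TGF-beta genes fell in 5 of 16, inflammatory genes in 3 of 12, neural progenitor markers in 4 of 15 against 1 that rose, and endothelium and endoderm markers in 2 of 12, KDR by 1.07 ± 0.13 on the log2 scale. Their adjusted p was 0.44, 0.224, 0.196 and 0.427 with an estimated correlation. Cohesin genes passed upwards with STAG1 at 0.54 ± 0.09, and histone genes with 0 called members (adjusted p = 0.224 and 0.707 with an estimated correlation).

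Cardiomyocyte markers did not pass as a list, with 9 lower and 4 higher of 38 (13 and 7 adjusted over the list alone). Of 28 neuron markers 5 fell, with ROBO2 at −1.78 ± 0.25 and MAP2 at −1.24 ± 0.12, and this list did not pass either. Clustered protocadherins had 0 called of 13 with a median of −0.29, and pluripotent cell markers 0 of 7. The other 7 lists tested did not pass. In total 680 genes were lower and 220 higher of 18647 in the joint fit of cardiomyocytes and neurons, and 239 and 52 of 17121 in cardiomyocytes fitted alone. Among the genes named by rule, 21 no longer passed in cardiomyocytes fitted alone and 29 kept their direction and side of the threshold. With the replicate number as a block the count was 359. Deviations of same-numbered cardiomyocyte libraries had a correlation of −0.245, so the numbers do not pair them, and with crossed numbers more genes were called.

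**Figure D3:**
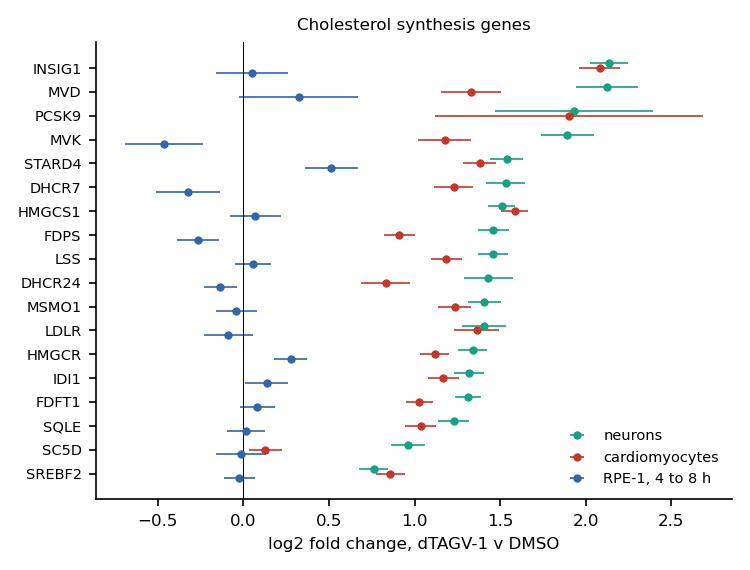
Log2 fold change of dTAGV-1 over DMSO (points, with SE as bars) for each cholesterol synthesis gene tested in neurons, cardiomyocytes and RPE-1 at 4 to 8 h. Medians were 1.44 in neurons, 1.18 in cardiomyocytes and 0.02 in RPE-1, the last turning to −0.02 under scaling by all reads.

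In neurons, cholesterol synthesis genes rose as well. INSIG1 rose by 2.14 ± 0.11, from 61.6 ± 5.95 to 271 ± 31.8 CPM (SD, 2 libraries each, adjusted p = 4.3e-06), and the mevalonate enzymes MVD and MVK by 2.12 ± 0.18 and 1.89 ± 0.16. Relative to all reads of each gene these were at 0.11, 0.93 and 0.34, of which MVD passed. RHOU, a small GTPase, fell by 2.33 ± 0.11, from 157 to 31.1 CPM, and NRP1, a receptor of axon guidance, by 1.99 ± 0.12, from 130 to 32.7 CPM. CDH20, a cadherin gene, was at −2.32 ± 0.29, MEF2C, a factor of muscle and neurons, at −1.33 ± 0.11 and VLDLR, a receptor for lipoproteins and reelin, at −1.37 ± 0.13. STAG1 rose by 0.70 ± 0.09.

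Cholesterol synthesis genes rose in 17 of 18 (18 adjusted over the list alone), with a median of 1.44 and adjusted p = 0.00173 with an estimated correlation. Neuron markers fell in 2 of 28 (6 adjusted over the list alone), NEFM by 0.83 ± 0.17 and NCAM1 by 0.66 ± 0.11 on the log2 scale. YAP targets fell in 3 of 19 (4 adjusted over the list alone), with F3 at −1.68 ± 0.30, and matrix genes in 2 of 31 (4 adjusted over the list alone), with HAS2 at −1.49 ± 0.22. TGF-beta genes fell in 1 of 16 (4 lower and 1 higher adjusted over the list alone) and immediate early genes in 1 of 28, which was JUN. With an estimated correlation the adjusted p of these 5 lists was 0.403, 0.433, 0.572, 0.572 and 0.709. G1 and S phase, histone and ribosomal protein lists passed downwards with 0 called members (adjusted p = 0.403, 0.97 and 0.433 with an estimated correlation). Cardiomyocyte markers had a median of −0.00, a mean of 0.08 and a test that pointed down, without a call, and the other 12 lists tested did not pass.

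There were 310 lower and 107 higher genes in neurons in the joint fit, and 806 and 407 in neurons fitted alone, so which cell type had more called genes depended on the fit. Libraries of the same group differed more in cardiomyocytes, with a chi-square per degree of freedom of 6.42 (DMSO) and 7.27 (dTAGV-1). In neurons it was 1.73 and 2.22. The spread shared in the joint fit may thus be too small for cardiomyocytes and too large for neurons. In neurons scaled by all reads, the median of all genes moved by −0.121, and 558 genes were lower and 67 higher. Leaving out 1 neuron library gave 159 or 151 called genes for DMSO replicates 1 and 2 and 168 or 133 for the dTAGV-1 ones, and leaving out either dTAGV-1 cardiomyocyte library gave 636. With the replicate number as a block 188 were called. The drug effect differed between the cell types for 111 genes, 47 with a lower and 64 with a higher value in neurons. The effect was lower in neurons for NRP1, with a difference of −1.90 ± 0.15 on the log2 scale, and the calcium channel gene RYR2, at −1.51 ± 0.18. It was lower in cardiomyocytes for RGS4, at 2.30 ± 0.27, and MAP2, at 1.28 ± 0.16. With the replicate number as a block no gene passed this test of the difference. Same-numbered libraries had correlations of −0.245 in cardiomyocytes and 0.0639 in neurons, so the data do not bear out this block. DESeq2, and edgeR without the filter on low counts, called more genes. With neuron replicates 1 and 2 left out in turn, 12 and 3 passed for DMSO and 25 and 13 for dTAGV-1.

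Genes enriched in a cell type were called more often there than other genes, lower and, outside neurons, higher. Enriched genes were not matched in level with the other genes, so a greater power to call them cannot be told apart. In RPE-1 with 120 min of 4sU and drug from mitosis, 101 of 1507 RPE-1-enriched genes fell (6.70% against 1.59% of other genes), an odds ratio of 4.44 by Fisher's exact test, with adjusted p = 1.44e-26. Of 871 genes enriched in cardiomyocytes 82 fell there (9.41% against 3.36%, odds ratio 2.99), and of 1070 enriched in neurons 56 fell there (5.23% against 1.45%, odds ratio 3.77). RPE-1-enriched genes also fell more often in cardiomyocytes (89 of 823, odds ratio 3.54) and in neurons (30 of 823, odds ratio 2.37), and neuron-enriched genes in cardiomyocytes (57 of 1070, odds ratio 1.53). In their own cell type, enriched genes were also raised more often in RPE-1 (22 of 1507, odds ratio 4.80) and cardiomyocytes (40 of 871, odds ratio 4.70), so the enrichment was not particular to lowered genes there, while 11 of 1070 in neurons did not pass at adjusted p = 0.0923. Outside it they were raised less often in 2 cases, RPE-1-enriched genes in cardiomyocytes (2 of 823, adjusted p = 0.0141) and cardiomyocyte-enriched genes in neurons (0 of 871, adjusted p = 0.0182). At an enrichment of at least 3 on the log2 scale these 2 cases and the neuron-enriched genes in cardiomyocytes did not pass.

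**Figure D4:**
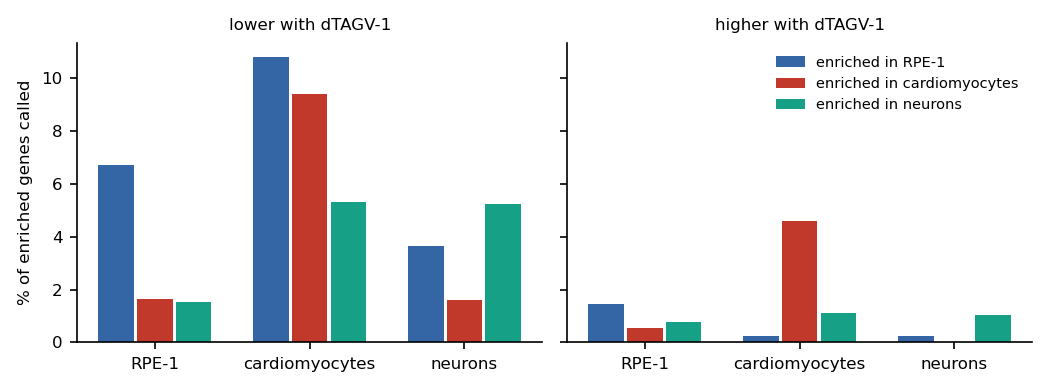
Percent of the genes enriched in each cell type that were called lower (left) or higher (right) with dTAGV-1 in RPE-1 with 120 min of 4sU, cardiomyocytes and neurons. Lowered genes made up 6.70% of RPE-1-enriched genes in RPE-1, 9.41% of cardiomyocyte-enriched genes in cardiomyocytes and 5.23% of neuron-enriched genes in neurons.

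Lowered genes overlapped between settings beyond the number that chance would give if every tested gene were equally likely to be called. Genes differ in level and spread, and some of these settings share 1 fit and its estimate of spread. Part of the excess may therefore come from a greater power to call the same genes, which was not tested. The series with 120 min of 4sU shared 79 lowered genes (2.19 by chance), among them SNAI2, IL6, BMP2 and HAS2. Drug from mitosis shared 90 with cardiomyocytes (11.2 by chance) and 39 with neurons (4.95 by chance), and the release series shared 35 (3.50 by chance) and 17 (1.55 by chance). Cardiomyocytes and neurons shared 145 lowered genes (11.3 by chance), among them VLDLR, IGFBP3 and CDH11, and 46 raised genes (1.26 by chance), among them INSIG1, HMGCS1 and STARD4. Lowered genes had a median length of 108 kb in the release average against 38.4 kb for all tested genes, 97.9 kb against 32.5 kb in cardiomyocytes and 182 kb against 32.5 kb in neurons. Raised genes had medians of 43.8, 67.3 and 44.5 kb. Over 30 to 120 min with drug from mitosis the medians were 53.2 kb for lowered, 86.1 kb for raised and 37.4 kb for all tested genes.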

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

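Every test of an explanation in this part, and every split of the libraries, was chosen only after the result was seen.

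Cholesterol synthesis genes rose in post-mitotic cardiomyocytes and neurons but had a median near 0 in RPE-1 at 4 to 8 h. An effect of the compound in every cell type is argued against by that RPE-1 median of 0.0152 (quartiles −0.09 to 0.08), far under 1.18 (1.03 to 1.35) in cardiomyocytes and 1.44 (1.32 to 1.54) in neurons. Scaling of the libraries is argued against as well, since at least 16 members still passed in each of these cell types with totals of all reads as library sizes. A compound effect that is smaller in RPE-1, one limited to these cells or their culture, and a response to the loss of NIPBL stay open. No library used here is known to lack the degron, and in these cells the degron itself is assumed. With 120 min of 4sU in RPE-1, all 17 members lay above 0 in the release series, with a median of 0.34, against 10 of 17 and a median of 0.05 in the mitosis series, so whether RPE-1 has a smaller change stays open.

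Longer genes tended to be higher with dTAGV-1 over 30 to 120 min in the mitosis series, with a Spearman correlation of 0.340 across genes, which are not independent replicates. A difference between sets of libraries may account for it, since replicates 1 and 2 alone gave −0.00912 and replicates 3 and 4 alone 0.359. These sets are unequal between arms. Replicate 1 of DMSO is absent at 0 and 30 min, and of dTAGV-1 replicate 4 at 30 min and replicate 3 at 120 min. A difference in conversion between long and short genes is argued against, because the change in converted share had a correlation of −0.0135 with length. With all reads in place of converted reads the correlation was 0.237, so the trend was not limited to newly made RNA. The DMSO library at 120 min with a large share of its reads in few genes is not the whole source, since 0.274 remained without it. No biological explanation was tested, and by time the correlation ran from −0.332 at 0 min to 0.503 at 120 min. Elsewhere it was −0.181 and −0.299 after 120 min of 4sU with drug from mitosis and from release, and −0.0361 in the release average. For DMSO at 120 min against 0 min it was −0.453.

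Genes lowered after 120 min of 4sU fell mostly from 90 min on with 15 min of 4sU in the mitosis series. Their median over 319 genes was −0.14 at 0, 30 and 60 min, −0.36 at 90 min and −0.55 at 120 min. A small shift was already present at 0 min, where 73.0% of them lay below 0, against 47.7% of all tested genes. Genes raised after 120 min of 4sU had a median of 0.26 at 0 min, with 21.7% below 0. The cause of this early shift was not tested. Low power at the early times is argued against as the whole account, since the median itself, at −0.139 at 60 min, was smaller and not only less certain. Dilution by converted reads that are background cannot be told apart from a late onset, because 19 such genes that had already risen 2-fold by 60 min in DMSO stood at −0.192 then and at −1.13 at 120 min, while in the release series they stood at −0.60 by 60 min. For the larger fall from 90 min on, a requirement for NIPBL that begins in early G1 stays open and was not tested further.

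Among 47 groups of measures per library, 2 single libraries lay far from the others, where chance gives about 1 in 20, or 2.35. Replicate 1 of dTAGV-1 at 60 min in the mitosis series had 2.32% of its converted reads in its top 10 genes, against 2.49% or more in the others. Replicate 3 of DMSO at 120 min had 13.4%, against 3.44% to 3.75%. The drug effect depended on time for 8 genes over 30 to 120 min in the mitosis series. It differed between drug from mitosis and drug from release for 14 genes, and between neurons and cardiomyocytes for 111. Without replicate 4 the first count was 1, without replicate 1 or 2 the second was 2, and without replicate 2 of the DMSO neurons the third was 3.

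In other splits of the same libraries, each time fitted alone, the real split gave the most genes with drug from mitosis at 120 min. It gave 38 genes against at most 8 in the other splits of the 35. The real split also gave the most for DMSO against 0 min at 60 min (5201 against 0), 90 min (2849 against 258) and 120 min (2119 against 275). The same holds for the average over 30 to 120 min with drug from mitosis (178 against 0), the release average (293 against 83) and the dependence on time (8 against 0). Each share is the smallest that so few splits can give and was not adjusted over the comparisons. These counts therefore argue against chance without excluding it. Chance cannot be excluded at 90 min with drug from mitosis, where 86 genes were called and 2 of the 35 splits reached this, the other with 685. That split set replicates 1 and 2 against replicates 3 and 4, which points to a structure of the samples, and with the replicate number as a block 96 genes were called at 90 min. Of the 8 splits that part libraries of the same number, only the real one called genes, but 8 are too few to decide. At 0 and 60 min no gene was called, so all 35 splits reach that by construction and say nothing about chance. The highest gave 31 genes at 60 min and 2383 at 0 min, where it set replicates 3 and 4 against the others and points to the same structure, while the 8 splits that part as many pairs gave 0.

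Chance cannot be excluded for the difference between mitosis and release series, with 14 genes against 21 and 2 of 30 splits as large. After 120 min of 4sU that difference gave 0 genes, so all 60 splits reach it by construction and say nothing about chance, and the highest gave 147. The 10 splits are too few for a share under 0.05 at 30 min with drug from mitosis (0 against 677) and in DMSO at 30 min (0 against 58). They are also too few after 120 min of 4sU with drug from mitosis (165 against 0) and with drug from release (136 against 0).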

How the results depend on the processing

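Results with each gene's converted reads relative to its all reads, with replicates 1 and 2 or 3 and 4 alone, with crossed replicate numbers, and without replicate 3 of DMSO at 120 min or of dTAGV-1 at 30 min were chosen after seeing the data. Of 4830 values of 329 named genes under the alternatives, 3964 kept their direction and side of the threshold, 820 kept their direction and no longer passed, 1 newly passed and 45 changed sign. Depth limited which genes could be tested, since 14208 of 36268 passed the filter on low counts in the mitosis series with 15 min of 4sU. Of simulated 1.5-fold changes 68% were recovered in its average over 30 to 120 min and 12% with 120 min of 4sU. The libraries with 120 min of 4sU hold more converted reads but are fewer per arm. These rates therefore cannot show whether depth limits small changes. Unless stated, the cause was not tested.

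With DESeq2 the calls were 85 at 90 min with drug from mitosis, 21 for the dependence on time, 656 with 120 min of 4sU and drug from mitosis, 256 with drug from release, 21 for their difference and 194 for neurons against cardiomyocytes. Without the filter on low counts, more genes were tested and the calls with drug from mitosis were 27 at 0 min, 7 at 30 min, 7 at 60 min, 120 at 90 min, 482 at 120 min, 359 in the average and 107 for the dependence on time. They were 72 in DMSO at 30 min, 27 for mitosis against release, 790 and 294 with 120 min of 4sU, 36 for their difference, 1725 in cardiomyocytes, 831 in neurons and 523 for their difference, and NIPBL was at −0.0153 with 120 min of 4sU and drug from mitosis.

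With the replicate number as a block the calls were 96 at 90 min, 211 at 120 min and 336 in the average with drug from mitosis, 495 in the release average, 833 and 282 with 120 min of 4sU and 14 for their difference. They were 359 in cardiomyocytes, 188 in neurons and 0 for their difference, and the block turned the cardiomyocyte list in DMSO at 120 min upwards (adjusted p = 0.973) and NIPBL in the release series with 120 min of 4sU to 0.000450. With crossed replicate numbers in the block 2087 genes were called in cardiomyocytes.

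With all reads the calls were 51 in the average with drug from mitosis, 82 in the release average, 66 and 23 with 120 min of 4sU, 512 in cardiomyocytes and 187 in neurons, RPL34 was at 0.0103 at 4 to 8 h and NIPBL at −0.19 with 120 min of 4sU and drug from mitosis. All reads also hold RNA made before the label. Scaled by all reads they were 111, 62, 212 and 50 in the averages and with 120 min of 4sU, and NIPBL was at 0.12 in DMSO at 120 min and 0.0224 in the release series with 120 min of 4sU.

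Relative to all reads of each gene, the calls were 46 in the average with drug from mitosis, 144 in the release average, 2584 in DMSO at 120 min, 174 at 4 to 8 h, 167 and 26 with 120 min of 4sU, 306 in cardiomyocytes and 137 in neurons. In DMSO at 120 min against 0 min this turned CCDC146 to 0.0523, CNTNAP2 to 0.47, DNMT3B to 0.49 and NIPBL to 0.39. It turned HIST1H1E to −0.24, JUNB to −2.10, DUSP5 to −0.11, GADD45A to −0.19, IL6 to −0.16, SNAI1 to −0.60, PLK3 to −0.39, INSIG1 to −0.30, POLR2C to −0.0246, POLR2E to −0.18, EEF2 to −0.0841, HES1 to −0.97 and SOX9 to −0.38. At 4 to 8 h it gave LINC01510 at −0.0950, LURAP1L-AS1 at −0.0574, MYC at 0.0170, SPRY4 at 0.0907, IL1B at 0.0334 and RUNX2 at 0.0577. Elsewhere KLF10 was at 0.00355 in the average with drug from mitosis, NIPBL at −0.0315 in the release average, ZFP36 at −0.0174 with 120 min of 4sU and drug from mitosis, and SPRY4 at 0.0277, IL6 at 0.0599 and NIPBL at 0.0406 in the release series with 120 min of 4sU. In cardiomyocytes INSIG1 was at −0.00286 and NIPBL at −0.0404, and in neurons BAMBI was at 0.0254, SOX9 at 0.0180, ETS1 at 0.0738 and NIPBL at −0.0323.

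The mitosis series alone with 120 min of 4sU gave 165 calls, cardiomyocytes alone 291 and neurons alone 1213. An absolute log2 change of at least 1 left 23 genes in the average with drug from mitosis, 468 at 4 to 8 h, 16 in the release average, 234 and 76 with 120 min of 4sU, 352 in cardiomyocytes and 147 in neurons, which is fewer by construction. Replicates 1 and 2 alone gave 13 calls at 90 min, 97 in the average and 2 for the dependence on time with drug from mitosis, and 2780, 1909 and 2037 in DMSO at 60, 90 and 120 min. Replicates 3 and 4 alone gave 14 at 90 min, 15 at 120 min, 70 in the average and 1 for the dependence on time, and 3193 and 2330 in DMSO at 60 and 120 min.

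Lists called with an estimated correlation numbered 0 in the average with drug from mitosis, 0 at 4 to 8 h, 2 with 120 min of 4sU and drug from mitosis, 2 in the release average, 0 in the release series with 120 min of 4sU, 1 in cardiomyocytes, 1 in neurons and 2 in DMSO at 120 min. At an enrichment of at least 3 on the log2 scale the odds ratio of RPE-1-enriched genes among those raised in cardiomyocytes was 0.234, of cardiomyocyte-enriched genes among those raised in neurons 0, of neuron-enriched genes among those lowered in cardiomyocytes 1.29 and among those raised there 1.01. From calls without the filter on low counts, the shared lowered and raised genes were 195 and 14 between the series with 120 min of 4sU, 208 and 11 between drug from mitosis and cardiomyocytes and 115 and 6 for neurons. They were 129 and 7 between drug from release and cardiomyocytes and 74 and 3 for neurons, and cardiomyocytes and neurons shared 321 lowered genes.

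Leaving out 1 replicate at a time, the calls with drug from mitosis ran from 11 (without replicate 4) to 40 at 90 min, with 16 without replicate 2 and 33 without replicate 1. They ran from 23 (without replicate 2) to 164 at 120 min, with 29 and 64 without replicates 4 and 1. The average ran from 57 (without replicate 4) to 217, the dependence on time from 1 (without replicate 4) to 15 (without replicate 3 of DMSO at 120 min), with 2 and 5 without replicates 2 and 1. In DMSO they ran from 2976 (without replicate 4, 3372 without replicate 2) to 4460 at 60 min, from 2021 (without replicate 4) to 3024 at 90 min and from 2489 (without replicate 4, 2515 without replicate 2) to 3856 at 120 min. For mitosis against release they ran from 2 (without replicate 1 or 2) to 8, with 7 without replicate 3. With 120 min of 4sU they ran from 76 (without replicate 2) to 263 with drug from mitosis and from 2 (without replicate 2, 27 without replicate 1) to 91 with drug from release. The release average ran from 106 (without replicate 2, 118 without replicate 1) to 258. Cardiomyocytes ran from 621 to 1381 (without dTAGV-1 replicate 1), neurons from 133 (without dTAGV-1 replicate 2) to 636 (without either dTAGV-1 cardiomyocyte library). Their difference ran from 3 (without neuron DMSO replicate 2) to 365 (without cardiomyocyte dTAGV-1 replicate 1), with 12, 25 and 13 without the other neuron libraries. NIPBL ran from −0.10 to 0.14 and from −0.20 to 0.19 with 120 min of 4sU, and from −0.0572 to 0.0573 in the release average. Where an arm was left with 1 library, that library was assumed to vary like the other groups.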

Other observations

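The tests of fatty acid genes and of genes that rise after mitosis were chosen only after the result was seen, and the count of neighbours was planned.

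Fatty acid synthesis genes, which share the SREBP transcription factors with the cholesterol pathway, also rose in the post-mitotic cells. Of 15 genes listed after the cholesterol result was seen, 8 rose in cardiomyocytes (10 adjusted over the list alone, median 0.45) and 11 in neurons (median 0.77), and none fell. The list also held genes that are not enzymes of fatty acid synthesis. TMEM97 and PNPLA3 are among them, and both are counted as raised in each cell type. The desaturase gene SCD rose by 0.97 ± 0.09 (SE, 2 libraries per arm) on the log2 scale in cardiomyocytes and 1.11 ± 0.08 in neurons. FASN, the fatty acid synthase, rose by 0.73 ± 0.16 and 1.00 ± 0.15, and PNPLA3, a lipase gene, by 1.16 ± 0.15 and 1.52 ± 0.15. ACSS2, which makes acetyl-CoA from acetate, rose by 1.36 ± 0.12 in neurons and was at 0.21 ± 0.12 in cardiomyocytes, where it did not pass. The list test gave p = 0.000737 in cardiomyocytes and 0.000104 in neurons with an estimated correlation. The list was written after results from these same libraries were seen, so these p-values are not independent support. A wider activation of SREBP targets may account for both groups, but SREBP activity itself was not measured.

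STAG1 was above 0 with dTAGV-1 in 7 of 7 main comparisons of the drug and passed the test in 5 of them. It was at 0.42 ± 0.11 over 30 to 120 min and 0.84 ± 0.08 at 4 to 8 h with drug from mitosis, 0.27 ± 0.06 in the release average, 0.54 ± 0.09 in cardiomyocytes and 0.70 ± 0.09 in neurons. After 120 min of 4sU it was at 0.49 ± 0.15 in each series, which did not pass. STAG1 encodes the cohesin subunit that can stand in for STAG2.

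Genes lowered with dTAGV-1 had fewer transcribed neighbours than matched genes, which had been predicted for genes that depend on NIPBL. The prediction restates what was counted, so its outcome does not show why these genes have few neighbours. Genes too low to be tested were not counted, so gene-poor regions are not shown. The median number of tested genes starting within 500 kb of a lowered gene was 6 with drug from mitosis after 120 min of 4sU, 5 in the release series, 5 in cardiomyocytes and 3 in neurons. Matched genes gave 7 to 8, 7 to 9, 7 to 8 and 6 to 7 (95% of 10000 draws). The one-sided permutation p was 0.0026 and 2e-04 in the RPE-1 series, and 1e-04, the smallest they can give, in both other cell types. Matching on enrichment in the cell type as well gave the same medians below the matched range. Each match was within bins of level and length, so lengths may still differ within the bin of the longest genes. Genes that rose had medians of 9, 7 and 9 neighbours with drug from mitosis, in cardiomyocytes and in neurons, within the range of matched genes. Their means were 9.56 against 11.2 in matched genes with drug from mitosis and 9.48 against 10.4 in cardiomyocytes. The one-sided permutation p of these means was 0.0305 and 0.0326, or 0.0858 and 0.121 with enrichment matched as well. In neurons the means were alike, at 11.2. The 12 genes that rose in the release series had a median of 3.5, below 5.5 to 15.5, so few neighbours may not be particular to lowered genes.

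Of 319 genes lowered after 120 min of 4sU with drug from mitosis, 124 (38.9%) had risen from 0 to 120 min in DMSO, against 14.6% of all tested genes and 11.9% to 20.1% of genes matched in level. Genes raised by the drug were over-represented alike, with 23 of 60 (38.3%), so this does not point to lowered genes in particular, and a need for NIPBL in switching genes on after mitosis cannot be told apart from a wider link between drug response and regulation after mitosis.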
